A study of Homo sapiens with 24 samples.

How the data were processed

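The series holds RNA-seq and ribosome profiling of 2 human multiple myeloma cell lines, MM.1S and NCI-H929 (called H929 here), each as a parental line and as a derivative made resistant to omacetaxine, a drug that blocks the ribosome's peptidyl transferase centre. Each of the 8 groups of line, state and assay had 3 libraries, 24 in all. Groups and replicate numbers came from the labels. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Neither line had a further resistant derivative. Changes with resistance here cannot be told apart from other differences between a derivative and its parent.

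Per the labels' protocols, RNA-seq libraries were made from poly(A)-selected RNA. Ribosome footprints were made by RNase I digestion of lysates containing cycloheximide, recovery of monosomes, depletion of rRNA and size selection on a gel. Footprint libraries carried single-index adapters and RNA-seq libraries dual-index adapters. The authors deposited 1 table of expected counts (estimated counts that need not be whole) for 57808 gene IDs and 24 libraries. The submitters' processing notes name cutadapt, UMI-tools, Salmon 1.6, DESeq2 and the build GRCh38. Which tool made which value, the transcript annotation, the strand setting and any filter are not given in the sources used here. Because strand handling is not stated, overlapping and antisense genes cannot be told apart, and genes with near-identical copies, such as histone genes, ribosomal protein genes and pseudogenes, are uncertain where counting could split reads between copies.

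The deposited estimated counts were rounded to whole numbers, which changed 18.8% of values. Symbols came from a table pairing gene IDs with names: 57030 of the 57808 IDs were in it and 41495 had a symbol. Biotype and positions came from a RefSeq table of GRCh38.p14, matched by symbol, for 40083 IDs. Total counts per library were 22478339 to 29405594 for RNA-seq and 4798059 to 24786936 for footprints. A count of 3 in 1 library, taken as the detection floor, corresponded to 0.102 to 0.133 CPM (counts scaled to a fixed library total) in RNA-seq and 0.121 to 0.625 CPM in footprints. Counting intervals and floors cover counting error only.

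Differences were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr by group, and the robust quasi-likelihood F test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 12 RNA-seq libraries shared 1 fit and the 12 footprint libraries another, with 1 mean per group. Translational efficiency, the ratio of footprints to RNA, was tested as the interaction of assay and state in 1 model over both kinds of library, per line. All changes are relative to the other genes, so a change of RNA or translation common to all genes cannot be seen. Differences between lines are MM.1S minus H929. Standard errors were derived from the F statistic. For a gene with few counts in a group, the fitted fold change depends on the prior count; where a group held 1 to 3 counts in all, the ratio of pooled counts with its exact 95% binomial interval is given. Each test was also tested on simulated data drawn from the libraries' own means and sizes, with 200 genes changed by known folds. At a 4-fold change the tests recovered 92.4% (MM.1S) and 93.2% (H929) of changed genes in RNA, 59.0% and 54.0% in footprints, and 87.3% and 95.2% in translational efficiency. At a 2-fold change these were 83.1%, 85.9%, 11.9%, 7.94%, 37.3% and 82.8%, leaving out changed genes that the filter removed. Each simulation gave fewer calls than the real libraries, which makes the adjusted threshold stricter, so these shares need not hold for the real tests. Unchanged genes made up 0% to 8.02% of simulated calls per test, and over 5% in H929 RNA (8.02%), MM.1S and H929 translational efficiency (5.62% and 7.58%) and the difference in RNA (6.06%). For translational efficiency the simulation gave RNA and footprint counts of a gene 1 shared spread, although footprints varied more between replicates. Its shares for translational efficiency therefore may not hold for the real libraries.

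A set of 30 gene lists was fixed before the data were examined, as were the main tests and most alternatives. They cover cytosolic ribosomal proteins, other TOP mRNAs (mRNAs with a 5' terminal oligopyrimidine tract), mTOR pathway components, translation initiation factors, aminoacyl-tRNA synthetases, mitochondrial ribosomal proteins, nuclear-encoded oxidative phosphorylation and mitochondrially encoded proteins. Others cover ATF4 and integrated stress response targets, amino acid transporters, ER chaperones and the unfolded protein response, proteasome subunits, lysosome and autophagy, glycolysis, cholesterol synthesis, cell cycle genes, replication-dependent histones, ribosome biogenesis factors and the BCL2 family. The rest cover interferon-stimulated genes, MHC class I and class II presentation, NF-kB targets and subunits, multidrug ABC transporters, plasma cell identity, and markers of B cells, T and NK cells, myeloid cells, erythroid and megakaryocyte cells and stromal cells. Of the listed symbols, 4 were not matched. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of each comparison.

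The rule for named genes was fixed before the data were examined. It allows the 6 largest increases and 6 largest decreases per comparison (at least 10 CPM, no overlap between replicates, which chance gives 10% of genes with 3 against 3), up to 4 members with the smallest p of each list past the threshold, 4 differences between lines per sign, and 8 genes for line identity. It also names 12 genes in every comparison whether or not they passed: ABCB1, MTOR, RPL3, MYC, MCL1, IRF4, EIF4EBP1, RPS6, DDIT4, DEPTOR, TXNIP and ATF4. Not all genes the first parts allow are named, and that selection was made after values were seen. Some genes are not reported here. IGLC1 and the genes named in the weighing of footprints without RNA lie outside the rule and were chosen after their values were seen.

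Alternatives were DESeq2 1.42.0, edgeR with DESeq2's size factors, no filter on low counts, other samples in the fit, a replicate block, and each library left out in turn. Fits on protein-coding genes, list tests without the replicate 2 footprint library of resistant H929, and list tests on differences between lines were added after seeing the data. Replicate pairs were compared before averaging: none of the 24 pairs held identical values, and chi-square per degree of freedom ranged from 3.03 to 580.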

Results

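RNA levels and ribosome footprints were measured in 2 multiple myeloma cell lines, MM.1S and H929, each as the parental line and as a line made resistant to omacetaxine, with 3 libraries per group. RNA-seq totals were 22478339 to 26717138 counts in MM.1S and 25054336 to 29405594 in H929. Footprint totals were 12482087 to 24786936 counts in MM.1S and 4798059 to 16180274 in H929. Protein-coding genes took 92.9% to 95.4% of RNA-seq counts but 23.4% to 53.2% of footprint counts. In H929 footprints the share was 23.4% to 39.2%. The lowest was in replicate 2 of the resistant H929 footprints, where 1 unnamed gene took 20.2% of all counts. Values are log2 fold changes of resistant against parental ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p, with 3 libraries against 3.

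MAF, ITGB7, NSD2 and FGFR3 and the light chain gene IGKC went with the known marks of the 2 lines. The lambda genes fixed in advance, IGLC2 and IGLC3, did not, while IGLC1, added after its value was seen, was high in MM.1S. The heavy chain gene IGHA1 was low in both lines. MAF and ITGB7, genes raised in lines with the t(14;16) translocation, were at 502 ± 100 and 18850 ± 524 CPM (SD, n = 3) in parental MM.1S and at 44.3 ± 6.81 and 3526 ± 267 CPM in parental H929. NSD2 and FGFR3, raised in t(4;14) lines, were at 790 ± 41.7 and 6.59 ± 1.66 CPM in parental H929 against 178 ± 18.7 and 0.175 ± 0.0352 CPM in parental MM.1S. The kappa light chain gene IGKC was at 9172 ± 679 CPM in parental H929 and 1.17 ± 0.0999 CPM in parental MM.1S, and IGHA1 was at 4.82 ± 0.472 and 17.4 ± 1.52 CPM. The lambda genes IGLC2 and IGLC3 were low in parental MM.1S, at 1.83 ± 0.0894 and 0.467 ± 0.0470 CPM, while IGLC1 was at 13310 ± 878 CPM there and 206 ± 24.9 CPM in parental H929. In resistant cells IGKC was at 7167 ± 164 CPM in H929 and IGLC1 at 10460 ± 537 CPM in MM.1S.

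The first comparison asked how RNA levels of resistant MM.1S differed from its parent. Targets of ATF4, the transcription factor of the integrated stress response, fell together, as did amino acid transporters, cell cycle genes and cholesterol synthesis genes. Histone genes, interferon-stimulated genes and MHC class II genes rose. Of 16260 genes tested, 9936 passed the threshold, 4881 higher and 5055 lower in resistant cells. The ATF4 list had 25 of 26 measured members lower and 1 higher, with a median of -2.53 (camera adjusted p = 3.15e-58, and adjusted p = 9.83e-05 with an estimated correlation). Its members PSAT1 and PHGDH, enzymes of serine synthesis, fell to -7.20 ± 0.10 and -5.48 ± 0.11, and CBS, an enzyme of transsulfuration, to -7.39 ± 0.17. DDIT4, an inhibitor of mTORC1 (ENSG00000168209.4, chromosome 10, 72273924 to 72276036 in GRCh38), was at -4.74 ± 0.10 (adjusted p = 4.59e-19). CHAC1, which degrades glutathione, and SLC7A11, a cystine transporter, were at -8.32 ± 0.22 and -7.70 ± 0.25. Amino acid transporters were lower for 16 of 17 members (adjusted p = 1.23e-20, and adjusted p = 0.00121 with an estimated correlation), among them SLC6A9 at -7.13 ± 0.15, SLC1A5 at -3.34 ± 0.09 and SLC1A4 at -2.78 ± 0.08. Aminoacyl-tRNA synthetases had 13 of 22 members lower and 7 higher (adjusted p = 7.56e-05, and adjusted p = 0.0245 with an estimated correlation), with GARS1 at -2.46 ± 0.07 and AARS1 at -2.24 ± 0.09.

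Cell cycle genes were lower for 32 of 37 members and higher for 1 in resistant MM.1S RNA, with a median of -1.20 (adjusted p = 7.42e-18, and adjusted p = 9.83e-05 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, MCM6, of the replicative helicase, and BIRC5 fell to -1.87 ± 0.07, -1.82 ± 0.07 and -1.77 ± 0.08, and CDKN1A, an inhibitor of cyclin-dependent kinases on the same list, to -1.81 ± 0.07. Replication-dependent histones were higher for 21 of 22 members, with a median of 3.68 (adjusted p = 1.71e-16, and adjusted p = 0.00336 with an estimated correlation), including H2BC8 at 5.00 ± 0.20, H2BC5 at 4.97 ± 0.15, H1-2 at 4.28 ± 0.12 and H2AC6 at 3.81 ± 0.10. Summed histone RNA was low in the parent, 20.1 ± 2.37 CPM, against 342 ± 11.8 CPM (SD, n = 3). Cholesterol synthesis genes were lower for 21 of 25 members and higher for 2 (adjusted p = 1.21e-15, and adjusted p = 0.00234 with an estimated correlation). INSIG1 was at -3.68 ± 0.08 and DHCR7 at -2.03 ± 0.07. ER chaperones and unfolded protein response genes were lower for 26 of 32 members and higher for 4 (adjusted p = 6.35e-07, and adjusted p = 0.0346 with an estimated correlation), with PDIA4 at -2.65 ± 0.08 and DNAJB9 at -1.79 ± 0.09. Plasma cell identity genes were lower for 11 of 22 and higher for 5 (adjusted p = 0.0255, but adjusted p = 0.114 with an estimated correlation and 0.105 with a replicate block). CAV1 was at -3.43 ± 0.12, GPRC5D at -2.28 ± 0.09 and DERL3 at -2.16 ± 0.09.

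Interferon-stimulated genes were higher for 28 of 38 members and lower for 2 in resistant MM.1S RNA (adjusted p = 1.9e-09, and adjusted p = 0.000814 with an estimated correlation), with ISG15 at 3.10 ± 0.13 and MX1 at 2.23 ± 0.08. MHC class II genes were higher for 10 of 13 (adjusted p = 2.06e-07, and adjusted p = 0.0473 with an estimated correlation). HLA-DQA1 was at 4.70 ± 0.20 and HLA-DRB1 at 1.5 ± 0.10. NF-kB targets and subunits were higher for 15 of 24 and lower for 5 (adjusted p = 0.00057, and adjusted p = 0.0473 with an estimated correlation), with BIRC3 at 2.67 ± 0.09 and ICAM1 at 2.38 ± 0.10. Ribosome biogenesis factors were higher for 39 of 50 and lower for 4 (adjusted p = 4.54e-06, and adjusted p = 0.0105 with an estimated correlation), with RRN3, an RNA polymerase I factor, at 1.25 ± 0.08 and DKC1 at 1.08 ± 0.07. Mitochondrial ribosomal proteins were higher for 55 of 76 and lower for 8 (adjusted p = 5.38e-07, but adjusted p = 0.519 with an estimated correlation). MRPL9 was at 1.20 ± 0.08 and MRPS33 at -1.5 ± 0.10. Cytosolic ribosomal proteins were lower for 64 of 79 and higher for 1, with a median of -0.52 (adjusted p = 0.000802, but adjusted p = 0.748 with an estimated correlation), with RPS3 at -0.99 ± 0.10 and RPLP0 at -0.91 ± 0.10. Other TOP mRNAs were lower for 18 of 29 and higher for 2 (adjusted p = 0.00057, but adjusted p = 0.439 with an estimated correlation). PABPC4 was at -1.75 ± 0.09 and PABPC1 at -1.29 ± 0.07. Counts adjusted over the list alone were the same except for 33 cell cycle genes lower and 11 MHC class II genes higher.

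The largest single increases in resistant MM.1S RNA included PXDN at 8.57 ± 0.24, ZBTB46 at 5.33 ± 0.24 and CD33, a myeloid marker, at 6.76 ± 0.26. RIMBP2 had 2 counts in all parental libraries and 4609 in all resistant ones, a ratio of 1980 (95% counting interval 547 to 16300). Among the largest decreases were SECTM1 at -8.51 ± 0.26, ASS1, an enzyme of arginine synthesis, at -8.46 ± 0.29, and ZNF544 at -7.75 ± 0.24. NOS3 had 843 parental and 3 resistant counts, a ratio of 328 (112 to 1590). CD33, SECTM1 and ZNF544 had 8, 5 and 4 counts in their lower group, so their fitted folds depend on the prior count. Of the 12 genes named in advance, EIF4EBP1, a repressor of cap-dependent translation under mTOR control, fell to -2.12 ± 0.09 and TXNIP rose to 2.07 ± 0.08. MCL1, an antiapoptotic BCL2 family member, rose to 1.23 ± 0.09 and MTOR (ENSG00000198793.12, chromosome 1, 11106535 to 11262551) to 0.71 ± 0.09. DEPTOR, an mTOR inhibitor, fell to -0.87 ± 0.06, ATF4 (ENSG00000128272.14, chromosome 22, 39520559 to 39522686) to -0.72 ± 0.08, IRF4 and RPL3 to -0.65 ± 0.08 each, RPS6 to -0.47 ± 0.11 and MYC to -0.39 ± 0.08. ABCB1, the drug efflux pump P-glycoprotein, was at -0.66 ± 0.37 and did not pass (adjusted p = 0.139). It passed only without replicate 3 of parental MM.1S RNA, at -0.96 (adjusted p = 0.0393).

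The same RNA comparison in H929 was led by the efflux pump gene. ABCB1 rose from 1 count in all parental libraries to 3858 in all resistant ones, a ratio of 3030 (95% counting interval 544 to 120000). Cell cycle genes and interferon-stimulated genes rose, while plasma cell identity genes fell. Of 16260 genes tested, 8063 passed, 3608 higher and 4455 lower. ABCB1 (ENSG00000085563.14) lies on chromosome 7, 87503017 to 87713295 in GRCh38. Interferon-stimulated genes were higher for 28 of 38 and lower for 6 (adjusted p = 5.2e-13, and adjusted p = 0.000564 with an estimated correlation), with IFI27 at 3.32 ± 0.10, PARP9 at 3.0 ± 0.14 and ISG15 at 1.99 ± 0.10. Cell cycle genes were higher for 28 of 37 and lower for 5 (adjusted p = 8.88e-09, and adjusted p = 0.00135 with an estimated correlation). CDK6 was at 1.86 ± 0.09, BUB1 at 1.14 ± 0.07 and PLK1 at 0.94 ± 0.07, while CCND1, cyclin D1, was at -2.68 ± 0.09. Plasma cell identity genes were lower for 14 of 22 and higher for 3 (adjusted p = 2.13e-06, and adjusted p = 0.0211 with an estimated correlation), with GPRC5D at -2.01 ± 0.09, SLAMF7 at -1.97 ± 0.08 and SDC1, the plasma cell antigen CD138, at -1.46 ± 0.08. Ribosome biogenesis factors were higher for 32 of 50 and lower for 2 (adjusted p = 1.43e-05, and adjusted p = 0.0221 with an estimated correlation). BRIX1 was at 0.83 ± 0.09, NCL at 0.71 ± 0.07 and POLR1D at -0.80 ± 0.08. Erythroid and megakaryocyte markers had 2 of 5 measured members higher and 1 lower (adjusted p = 0.000639, and adjusted p = 0.0368 with an estimated correlation, but 0.12 with a replicate block): HBB at 6.10 ± 0.17, HBG2 at 1.64 ± 0.41 and GP9 at -1.73 ± 0.46.

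Other lists passed in H929 RNA with the preset correlation only. Cytosolic ribosomal proteins were lower for 75 of 79 and higher for 1, with a median of -0.56 (adjusted p = 3.75e-08, but adjusted p = 0.557 with an estimated correlation), with RPL13A at -0.97 ± 0.11. Other TOP mRNAs were lower for 24 of 29 and higher for 1 (adjusted p = 2.13e-06, but adjusted p = 0.308 with an estimated correlation). PABPC4 was at -1.43 ± 0.09, EIF4A2 at -1.12 ± 0.08 and EEF2 at -0.84 ± 0.09. Lysosome and autophagy genes were lower for 26 of 40 and higher for 3 (adjusted p = 1.54e-06, but adjusted p = 0.106 with an estimated correlation), with the cathepsins CTSB, CTSA and CTSD at -1.53 ± 0.07, -1.52 ± 0.07 and -1.05 ± 0.08. Glycolysis genes were lower for 17 of 23 (adjusted p = 1.01e-05, but adjusted p = 0.187 with an estimated correlation), with ALDOC at -0.97 ± 0.08, GPI at -0.91 ± 0.08 and PFKFB4 at -0.90 ± 0.07. ER chaperones were lower for 22 of 32 and higher for 2 (adjusted p = 1.38e-05, but adjusted p = 0.0809 with an estimated correlation). DNAJB9 was at -1.44 ± 0.08, HERPUD1 at -1.32 ± 0.07 and PDIA4 at -1.10 ± 0.07. ATF4 targets were lower for 15 of 26 (adjusted p = 0.000176, but adjusted p = 0.151 with an estimated correlation), with CBS at -1.46 ± 0.11. Of mitochondrially encoded proteins 13 of 13 were lower (adjusted p = 2.93e-05, but adjusted p = 0.299 with an estimated correlation). MT-ND5 was at -1.03 ± 0.09 and MT-CO2 at -0.83 ± 0.09. Proteasome subunits were higher for 20 of 36 and lower for 1 (adjusted p = 0.00013, but adjusted p = 0.545 with an estimated correlation), with PSMC2 at 0.78 ± 0.07 and PSMD11 at 0.57 ± 0.06. Mitochondrial ribosomal proteins were higher for 37 of 76 and lower for 3 (adjusted p = 0.000203, but adjusted p = 0.628 with an estimated correlation). MRPS27 was at 1.09 ± 0.07 and MRPS5 at -0.96 ± 0.06. Translation initiation factors were higher for 16 of 32 and lower for 5 (adjusted p = 0.00943, but adjusted p = 0.299 with an estimated correlation), with EIF5 at 0.78 ± 0.07. When adjusted over the list alone, 29 cell cycle genes, 29 interferon-stimulated genes, 34 ribosome biogenesis factors, 3 erythroid and megakaryocyte markers and 2 other TOP mRNAs were higher, and 7 interferon-stimulated genes and 4 mitochondrial ribosomal proteins lower. The other counts were the same.

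Further large changes in resistant H929 RNA were increases of PTPRC, the leukocyte antigen CD45, at 8.13 ± 0.37, AHNAK at 4.10 ± 0.17, CD180 at 3.93 ± 0.17 and STON2 at 3.83 ± 0.11. Decreases included ICAM3 at -8.22 ± 0.20, NBDY at -7.51 ± 0.26, PCDHGC3 at -6.76 ± 0.42 and LGALS8 at -4.91 ± 0.14. PTPRC and NBDY had 4 and 5 counts in their lower group, so their folds depend on the prior count, and PCDHGC3 was at -11.44 without replicate 1 of the resistant RNA. Of the genes named in advance, TXNIP fell to -1.19 ± 0.08, DDIT4 to -1.02 ± 0.08 and RPL3 (ENSG00000100316.15, chromosome 22, 39312882 to 39319623) to -1.01 ± 0.09. ATF4 at -0.46 ± 0.08, RPS6 at -0.45 ± 0.11, EIF4EBP1 at -0.38 ± 0.08 and MYC at -0.35 ± 0.08 also fell, RPS6 to -0.29 without replicate 1 of the parental RNA. MCL1 at 0.56 ± 0.09 and MTOR at 0.44 ± 0.09 rose. IRF4 at -0.16 ± 0.08 (adjusted p = 0.0952) and DEPTOR at -0.14 ± 0.06 (adjusted p = 0.071) did not pass, and DEPTOR passed only with DESeq2, at -0.13 (adjusted p = 0.0195).

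**Figure D1:**
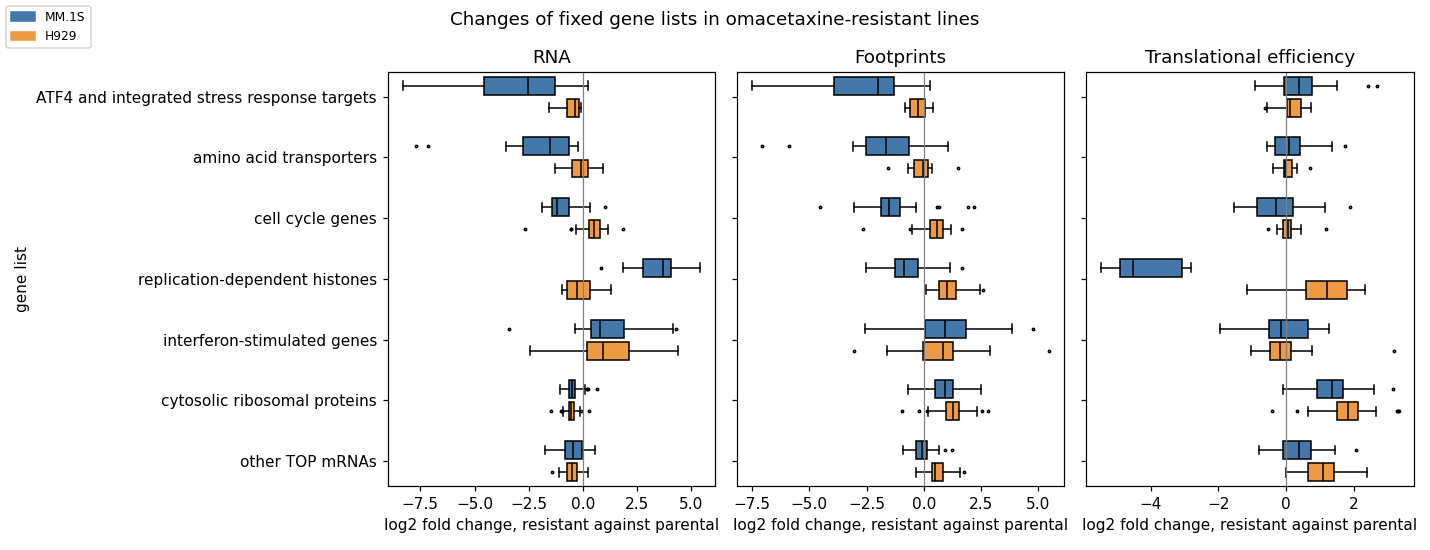
Log2 fold changes of resistant against parental cells for the members of 7 fixed gene lists, in RNA, footprints and translational efficiency, for MM.1S (blue) and H929 (orange). Boxes span the quartiles with the median as a line, whiskers reach 1.5 box lengths, and dots are members beyond them. Ribosomal protein genes had medians of 1.37 (MM.1S) and 1.84 (H929) in translational efficiency, and ATF4 targets a median of -2.53 in MM.1S RNA.

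In footprints of resistant MM.1S, ATF4 targets, amino acid transporters, cell cycle genes and cholesterol synthesis genes fell, while ribosomal protein mRNAs rose. Of 13197 genes tested, 5094 passed, 2678 higher and 2416 lower. The libraries themselves differed by state: the 10 largest genes held 64.9% to 67.3% of counts in parental libraries and 41.6% to 55.4% in resistant ones. Genes with any count numbered 13972 to 15901 and 17511 to 19173. Effects of such library differences cannot be told apart from resistance, here or in MM.1S translational efficiency. Cytosolic ribosomal proteins were higher for 56 of 79 members and lower for none, with a median of 0.94 (adjusted p = 6.74e-13, and adjusted p = 0.00695 with an estimated correlation). RPL39 was at 2.48 ± 0.16, RPS27 at 2.36 ± 0.14 and RPL11 at 1.72 ± 0.13. ATF4 targets were lower for 20 of 25 (adjusted p = 7.1e-25, and adjusted p = 0.000526 with an estimated correlation), with PSAT1 at -7.51 ± 0.32, PHGDH at -4.75 ± 0.29 and ASNS, asparagine synthetase, at -3.91 ± 0.18. Amino acid transporters were lower for 13 of 17 (adjusted p = 2.57e-12, and adjusted p = 0.00568 with an estimated correlation). SLC6A9 was at -5.87 ± 0.32, SLC1A5 at -3.03 ± 0.18 and SLC7A1 at -2.54 ± 0.18. Cell cycle genes were lower for 29 of 37 and higher for 4 (adjusted p = 3.6e-18, and adjusted p = 0.0035 with an estimated correlation), with MKI67 at -3.05 ± 0.16, TOP2A at -2.63 ± 0.14 and MCM6 at -2.31 ± 0.14. Cholesterol synthesis genes were lower for 17 of 25 and higher for 3 (adjusted p = 1.69e-07, and adjusted p = 0.00634 with an estimated correlation). INSIG1 was at -2.36 ± 0.19. Aminoacyl-tRNA synthetases were lower for 13 of 22 and higher for 3 (adjusted p = 1.62e-08, and adjusted p = 0.0482 with an estimated correlation), with GARS1 at -3.04 ± 0.12 and EPRS1 at -2.68 ± 0.13. Interferon-stimulated genes were higher for 15 of 35 and lower for 2 (adjusted p = 0.00015, and adjusted p = 0.0157 with an estimated correlation). ISG15 was at 3.85 ± 0.45 and MX1 at 2.08 ± 0.18.

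Mitochondrial ribosomal proteins had 40 of 76 members higher and 1 lower in resistant MM.1S footprints (adjusted p = 6.14e-06, and adjusted p = 0.0157 with an estimated correlation), with MRPL24 at 1.44 ± 0.12. Nuclear-encoded oxidative phosphorylation had 36 of 76 higher and 9 lower (adjusted p = 0.000611, and adjusted p = 0.0482 with an estimated correlation). ATP5F1E was at 2.68 ± 0.14 and SDHA at -1.31 ± 0.13. NF-kB targets were higher for 8 of 22 (adjusted p = 0.00329, and adjusted p = 0.0482 with an estimated correlation), with BIRC3 at 3.27 ± 0.31, CCL4 at 2.37 ± 0.20 and CD40 at 1.98 ± 0.25. Histones were lower for 21 of 36 and higher for 4 (adjusted p = 1.07e-05, but adjusted p = 0.146 with an estimated correlation). H2AC12 was at -1.86 ± 0.19 and H4C3 at -1.5 ± 0.12. MHC class II genes were higher for 7 of 13 (adjusted p = 0.00114, but adjusted p = 0.0539 with an estimated correlation), with HLA-DRA at 1.34 ± 0.15 and CTSS at 1.23 ± 0.13. ER chaperones were lower for 17 of 32 and higher for 4 (adjusted p = 0.00383, but adjusted p = 0.142 with an estimated correlation). PDIA4 was at -2.96 ± 0.12 and SPCS1 at 1.41 ± 0.12. Mitochondrially encoded proteins were lower for 9 of 13 (adjusted p = 0.00395, but adjusted p = 0.357 with an estimated correlation), with MT-ND2 at -1.67 ± 0.18. With p adjusted over the list alone, 61 ribosomal proteins, 41 mitochondrial ribosomal proteins, 37 oxidative phosphorylation genes, 19 interferon-stimulated genes, 8 MHC class II genes and 5 ER chaperones were higher. Likewise 31 cell cycle genes, 22 histones, 21 ATF4 targets, 19 cholesterol synthesis genes and 2 mitochondrial ribosomal proteins were lower, and the other counts were the same.

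Large single changes in resistant MM.1S footprints were PXDN at 4.29 ± 0.86, or 6.44 without replicate 1 of the parental footprints, and ASS1 at -7.84 ± 0.58, with 6 resistant counts and so a fold that depends on the prior count. Of the genes named in advance, DDIT4 fell to -4.57 ± 0.40, EIF4EBP1 to -1.76 ± 0.31, ATF4 to -1.57 ± 0.15, DEPTOR to -0.65 ± 0.15 and IRF4 to -0.53 ± 0.13. TXNIP rose to 1.95 ± 0.12, MCL1 to 1.25 ± 0.15 and RPS6 to 0.85 ± 0.20. MTOR at 0.23 ± 0.14 (adjusted p = 0.211), RPL3 at -0.15 ± 0.21 (0.619), MYC at -0.04 ± 0.14 (0.832) and ABCB1 at -0.02 ± 0.70 (0.997) did not pass.

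Footprints of resistant H929 rose on ribosomal protein mRNAs, other TOP mRNAs, histones, cell cycle genes and ABCB1, at the lowest depth of the 4 RNA and footprint comparisons. Of 13197 genes tested, 1139 passed, 579 higher and 560 lower. The count was 660, 637 and 621 without replicates 1, 2 and 3 of the parental footprints, 742 and 668 without replicates 1 and 3 of the resistant footprints, and 648 with a replicate block. Cytosolic ribosomal proteins were higher for 70 of 79 and lower for none, with a median of 1.28 (adjusted p = 1.1e-84, and adjusted p = 3.09e-05 with an estimated correlation). RPL37A was at 2.80 ± 0.19, RPS27 at 2.56 ± 0.15 and RPL11 at 1.82 ± 0.13. Other TOP mRNAs were higher for 12 of 29 (adjusted p = 1.14e-10, and adjusted p = 0.0162 with an estimated correlation), with EEF1G at 1.75 ± 0.14, EEF1A1 at 1.58 ± 0.15 and EIF3L at 0.95 ± 0.13. Histones were higher for 26 of 36 (adjusted p = 3.27e-27, and adjusted p = 0.0114 with an estimated correlation). H2BC4 was at 1.41 ± 0.14 and H4C3 at 1.40 ± 0.12. Cell cycle genes were higher for 17 of 37 and lower for 1 (adjusted p = 1.53e-08, and adjusted p = 0.013 with an estimated correlation), with CDK6 at 1.66 ± 0.24, PLK1 at 1.19 ± 0.16, MCM7 at 0.81 ± 0.12 and CCND1 at -2.66 ± 0.34. Interferon-stimulated genes were higher for 11 of 35 and lower for 5 (adjusted p = 2.63e-05, and adjusted p = 0.0162 with an estimated correlation). PARP9 was at 2.67 ± 0.34, SAMD9L at 1.66 ± 0.19 and IFI6 at 1.35 ± 0.18. Mitochondrial ribosomal proteins were higher for 18 of 76 and lower for 1 (adjusted p = 2.59e-08, and adjusted p = 0.0114 with an estimated correlation), with MRPS27 at 1.24 ± 0.15 and MRPS5 at -1.18 ± 0.13. Proteasome subunits were higher for 8 of 36 (adjusted p = 8.13e-06, and adjusted p = 0.0162 with an estimated correlation). PSMC2 was at 0.86 ± 0.13 and PSMD11 at 0.78 ± 0.13. ER chaperones were lower for 12 of 32 (adjusted p = 5.08e-09, and adjusted p = 0.0136 with an estimated correlation), with HERPUD1 at -1.38 ± 0.14 and PDIA4 at -1.26 ± 0.11. Lysosome and autophagy genes were lower for 8 of 40 (adjusted p = 5.04e-06, and adjusted p = 0.0495 with an estimated correlation). CTSB was at -1.36 ± 0.13 and PSAP at -1.17 ± 0.12.

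Other lists passed in H929 footprints with the preset correlation only. Mitochondrially encoded proteins were lower for 7 of 13 (adjusted p = 3.06e-07, but adjusted p = 0.0911 with an estimated correlation), with MT-ND2 at -1.27 ± 0.17 and MT-CO2 at -1.18 ± 0.19. Translation initiation factors were higher for 6 of 32 (adjusted p = 0.000686, but adjusted p = 0.224 with an estimated correlation). EIF1 was at 1.13 ± 0.17 and EIF3B at 0.99 ± 0.12. Plasma cell identity genes were lower for 8 of 22 and higher for 1 (adjusted p = 0.000686, but adjusted p = 0.063 with an estimated correlation), with SLAMF7 at -1.98 ± 0.16 and NCAM1 at -0.95 ± 0.14. Oxidative phosphorylation genes were higher for 13 of 76 and lower for 2 (adjusted p = 0.00104, but adjusted p = 0.063 with an estimated correlation). COX6B1 was at 0.95 ± 0.15. Glycolysis genes were lower for 5 of 23 (adjusted p = 0.002, but adjusted p = 0.224 with an estimated correlation), with GPI at -0.94 ± 0.15 and HK2 at -0.83 ± 0.12. Ribosome biogenesis factors were higher for 3 of 50 (adjusted p = 0.0048, but adjusted p = 0.234 with an estimated correlation). NPM3 was at 1.12 ± 0.20. Cholesterol synthesis genes were lower for 5 of 25 and higher for 1 (adjusted p = 0.0424, but adjusted p = 0.135 with an estimated correlation and 0.051 on protein-coding genes only). ATF4 targets were lower for 2 of 25 (adjusted p = 0.0431, but adjusted p = 0.236 with an estimated correlation, 0.0521 without replicate 2 of the resistant footprints and 0.051 on protein-coding genes only): PPP1R15A at -0.71 ± 0.13 and ATF4 itself at -0.63 ± 0.15. By counts adjusted over the list alone, 73 ribosomal proteins, 29 histones, 24 mitochondrial ribosomal proteins, 22 cell cycle genes, 20 other TOP mRNAs, 19 oxidative phosphorylation genes, 14 interferon-stimulated genes, 10 proteasome subunits, 2 plasma cell identity genes and 2 cholesterol synthesis genes were higher. Likewise 16 ER chaperones, 14 lysosome genes, 10 plasma cell identity genes, 9 mitochondrially encoded proteins, 7 glycolysis genes, 7 cholesterol synthesis genes, 4 oxidative phosphorylation genes, 2 cell cycle genes, 1 ribosomal protein, 1 other TOP mRNA and 1 initiation factor were lower.

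ABCB1 footprints in H929 rose by 3.94 ± 0.43 (adjusted p = 0.000156), from 74 pooled counts in the parent, which had 1 RNA count, to 1603, a ratio of 15.4 (95% counting interval 12.2 to 19.8). If the parental footprints are carry-over, this ratio and fold understate the rise. Other large changes were CD180 at 3.63 ± 0.62, and PDGFB at -4.40 ± 0.48, ICAM3 at -3.96 ± 0.36, MLC1 at -3.06 ± 0.21 and NCKAP1L at -3.00 ± 0.20. ANXA1, with 7 parental counts and so a fold that depends on the prior count, was at 5.19 ± 1.27 (adjusted p = 0.033). Its call was lost without replicate 1, 2 or 3 of the parental footprints (adjusted p = 0.122, 0.129 and 0.14) or replicate 2 of the resistant ones (3.45, adjusted p = 0.0575). RPS6 rose to 1.59 ± 0.21 and TXNIP fell to -0.80 ± 0.12. MCL1 at 0.53 ± 0.15 (adjusted p = 0.0392) lost its call without any 1 of parental replicates 1, 2 and 3 (adjusted p = 0.128, 0.144 and 0.123) or resistant replicates 1 and 3 (0.123 and 0.146), and ATF4 (adjusted p = 0.0169) without parental replicates 2 or 3 (0.0723 and 0.0983) or resistant replicate 3 (0.0884). EIF4EBP1 at 0.44 ± 0.34 (adjusted p = 0.528), DDIT4 at -0.47 ± 0.34 (0.492), DEPTOR at -0.40 ± 0.15 (0.133), IRF4 at -0.24 ± 0.13 (0.301), RPL3 at 0.17 ± 0.22 (0.734), MTOR at 0.09 ± 0.14 (0.801) and MYC at -0.03 ± 0.14 (0.946) did not pass.

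Translational efficiency addresses the translational change that the series title links to mTOR. In resistant MM.1S, histones had fewer footprints per poly(A)-selected RNA, and ribosomal protein mRNAs more with the preset correlation only. Replication-dependent histone mRNAs mostly lack poly(A) tails, so their ratio here is to the polyadenylated part and is not their translational efficiency. Of 11355 genes tested, 3558 passed, 1857 higher and 1701 lower. Histones were lower for all 17 measured members, with a median of -4.52 (adjusted p = 1.07e-51, and adjusted p = 0.000177 with an estimated correlation), with H4C8 at -4.75 ± 0.22, H1-2 at -4.52 ± 0.23 and H2AC6 at -3.23 ± 0.17. Cytosolic ribosomal proteins were higher for 69 of 79 and lower for none, with a median of 1.37 (adjusted p = 8.85e-35, but adjusted p = 0.196 with an estimated correlation). RPS12 was at 3.15 ± 0.27, RPS27 at 2.59 ± 0.17 and RPS20 at 2.58 ± 0.24. Other TOP mRNAs were higher for 11 of 29 and lower for 3 (adjusted p = 0.0157, but adjusted p = 0.595 with an estimated correlation), with TPT1 at 2.06 ± 0.18, PABPC4 at 1.45 ± 0.14 and PABPC1 at 1.33 ± 0.13. In footprints alone that list did not pass (camera adjusted p = 0.63), with a median of -0.09. BCL2 family genes were higher for 7 of 11 (adjusted p = 0.0136, but adjusted p = 0.196 with an estimated correlation). They included the antiapoptotic BCL2L1 at 1.53 ± 0.18 and BCL2 at 1.42 ± 0.30 and the proapoptotic BID at 1.42 ± 0.30 and PMAIP1 at 1.39 ± 0.28. Mitochondrially encoded proteins were lower for 9 of 13 and higher for 1 (adjusted p = 0.000589, but adjusted p = 0.39 with an estimated correlation). MT-ND2 was at -1.52 ± 0.16. Ribosome biogenesis factors were lower for 21 of 50 and higher for 4 (adjusted p = 0.0019, but adjusted p = 0.196 with an estimated correlation), with UTP20 at -2.44 ± 0.17. Aminoacyl-tRNA synthetases were lower for 12 of 22 (adjusted p = 0.00391, but adjusted p = 0.39 with an estimated correlation). EPRS1 was at -0.95 ± 0.15 and GARS1 at -0.64 ± 0.12. Oxidative phosphorylation genes were higher for 31 of 76 and lower for 9 (adjusted p = 0.0136, but adjusted p = 0.697 with an estimated correlation), with NDUFV2 at 2.05 ± 0.27 and ATP5F1E at 1.46 ± 0.16. Cell cycle genes were lower for 16 of 36 and higher for 5 (adjusted p = 0.0136, but adjusted p = 0.345 with an estimated correlation). MKI67 was at -1.54 ± 0.17 and TOP2A at -1.28 ± 0.14. Adjusted over the list alone, 14 other TOP mRNAs and 33 oxidative phosphorylation genes were higher, 4 other TOP mRNAs, 10 mitochondrially encoded proteins, 23 ribosome biogenesis factors and 17 cell cycle genes lower, and the other counts were the same.

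The mTOR pathway list passed in none of the 6 comparisons, with camera adjusted p = 0.254 (MM.1S) and 0.548 (H929) in RNA, 0.776 and 0.941 in footprints, and 0.609 and 0.868 in translational efficiency. Its members did change: of 42, 16 rose and 16 fell in MM.1S RNA, and 10 rose and 14 fell in H929 RNA. Of all tested genes, 61.1% and 49.6% passed there. The list holds MTOR and also inhibitors such as DDIT4 and DEPTOR, so a test for a shared direction can miss opposed changes. It does not measure mTOR activity. Among single genes in MM.1S, TOMM7 had a translational efficiency change of 3.03 ± 0.24, TUBA1A of -3.65 ± 0.42 and USP24 of -2.43 ± 0.20. WDR74 was at -4.47 ± 0.27, and it took 14.5% and 16.8% of all footprint counts in replicates 2 and 3 of parental MM.1S. Its value is uncertain, because reads of overlapping genes cannot be told apart, and its counts are part of the protein-coding share of those libraries. RPS6 rose to 1.26 ± 0.17, and ATF4 and MTOR fell to -0.91 ± 0.15 and -0.54 ± 0.16. The call of MTOR (adjusted p = 0.0206) was lost without replicate 3 of the parental or of the resistant RNA (adjusted p = 0.0638 and 0.0644) and without the filter (0.0582). RPL3 at 0.45 ± 0.27 (adjusted p = 0.223), MYC at 0.29 ± 0.18 (0.252), EIF4EBP1 at 0.30 ± 0.30 (0.482), TXNIP at -0.18 ± 0.13 (0.308), DEPTOR at 0.16 ± 0.16 (0.502), DDIT4 at 0.09 ± 0.39 (0.884), IRF4 at 0.05 ± 0.16 (0.826) and MCL1 at -0.04 ± 0.18 (0.88) did not pass, and ABCB1 was not tested in MM.1S.

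In H929, translational efficiency rose for ribosomal protein mRNAs and other TOP mRNAs. Footprints per poly(A)-selected RNA also rose for histones, with the same limit as in MM.1S. Of 9243 genes tested, 402 passed, 289 higher and 113 lower, 71.9% higher. DESeq2 called 762, of which 59.7% were higher, the count without replicate 2 of the resistant footprints was 850, with a replicate block it was 240, and it was 230 and 259 without replicates 1 and 2 of the resistant RNA. Cytosolic ribosomal proteins were higher for 72 of 78, with a median of 1.84 (adjusted p = 4.67e-162, and adjusted p = 0.00286 with an estimated correlation), with RPL37A at 3.32 ± 0.21, RPS27 at 3.30 ± 0.24, RPL28 at 3.28 ± 0.25, RPS19 at 2.54 ± 0.19 and RPL11 at 2.32 ± 0.17. Other TOP mRNAs were higher for 22 of 29 (adjusted p = 1.14e-35, and adjusted p = 0.00286 with an estimated correlation). EEF1A1 was at 2.40 ± 0.16, PABPC4 at 1.97 ± 0.15, EEF1G at 1.78 ± 0.19 and EIF3F at 1.43 ± 0.15. Histones were higher for 15 of 22 and lower for 1 (adjusted p = 2.56e-19, and adjusted p = 0.00286 with an estimated correlation), with H2AC8 at 1.81 ± 0.20 and H2AC6 at 1.56 ± 0.16. Oxidative phosphorylation genes were higher for 2 of 76 (adjusted p = 0.00261, but adjusted p = 0.796 with an estimated correlation). COX6B1 was at 1.12 ± 0.19. Mitochondrial ribosomal proteins were higher for 2 of 76 (adjusted p = 0.03, but adjusted p = 0.796 with an estimated correlation, and 0.0839 without replicate 2 of the resistant footprints). MRPL37 was at 0.65 ± 0.16 (adjusted p = 0.0265), and its call was lost without any 1 of the parental footprint libraries (0.061, 0.0798 and 0.0728), parental RNA replicates 1 and 2 (0.0569 and 0.0685) or resistant RNA libraries (0.0846, 0.0671 and 0.0591). Multidrug ABC transporters had 1 of 7 lower (adjusted p = 0.0195, but adjusted p = 0.436 with an estimated correlation), ABCB1 at -6.93 ± 0.53, a value that depends on the prior count because the parent had 1 RNA count, and on parental footprints that may be carry-over. Adjusted over the list alone, 74 ribosomal proteins, 26 other TOP mRNAs and 16 histones were higher, and the other counts were the same.

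Decreases in H929 translational efficiency included MIGA1 at -3.13 ± 0.52, ZNF292 at -1.18 ± 0.21, KAT6A at -1.17 ± 0.18, USP24 at -1.06 ± 0.15 and HELZ at -1.04 ± 0.18. The call of MIGA1 (adjusted p = 0.00745) was lost when both lines shared 1 fit (adjusted p = 0.208). RPS6 rose to 2.05 ± 0.28 and RPL3 to 1.18 ± 0.18. EIF4EBP1 at 0.82 ± 0.27 (adjusted p = 0.0966), DDIT4 at 0.56 ± 0.22 (0.172), MTOR at -0.34 ± 0.18 (0.34), MYC at 0.32 ± 0.14 (0.225), DEPTOR at -0.25 ± 0.15 (0.406), ATF4 at -0.16 ± 0.16 (0.661), IRF4 at -0.08 ± 0.14 (0.828) and MCL1 at -0.03 ± 0.16 (0.955) did not pass. TXNIP at 0.39 ± 0.14 did not pass (0.127) but passed with DESeq2 (6.8e-07) and without replicate 2 of the resistant footprints (0.0354).

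**Figure D2:**
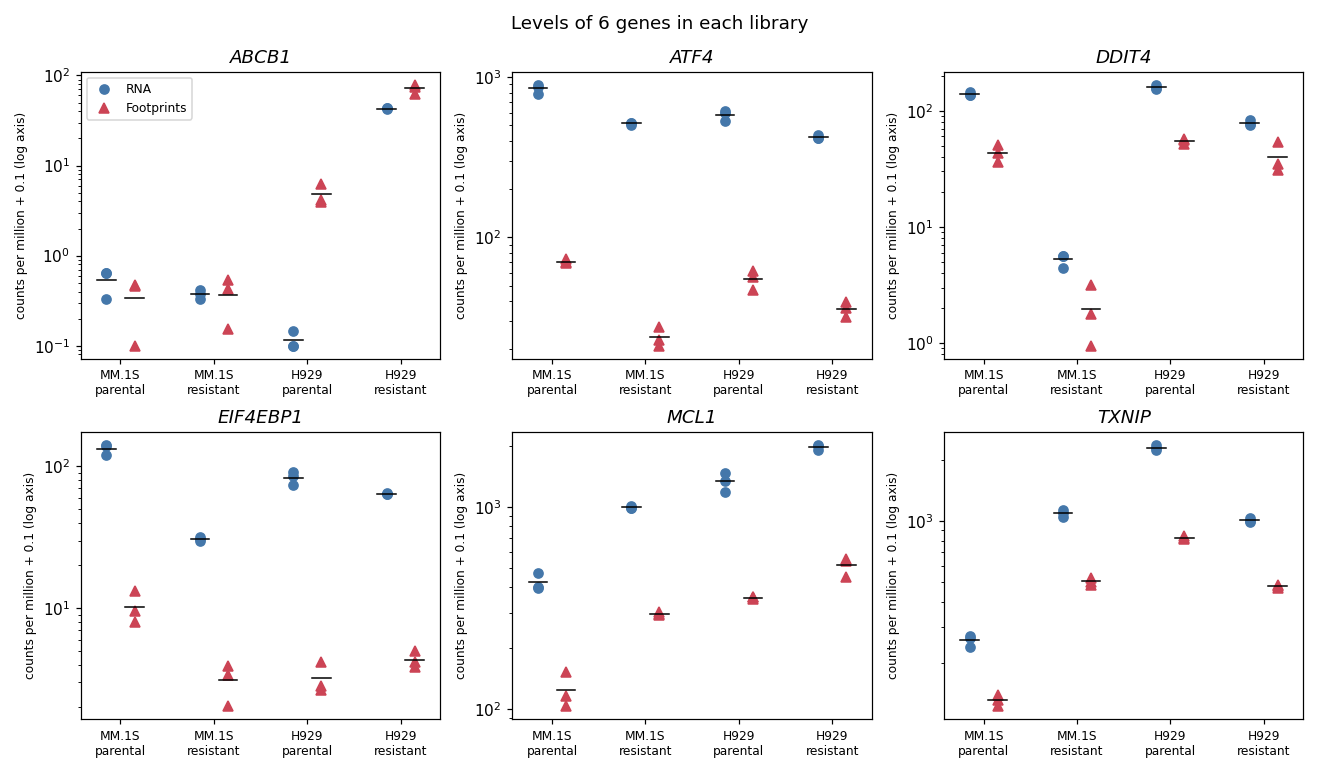
CPM plus 0.1, on a log axis, of 6 of the genes named in advance, chosen after their values were seen, in each library of the 4 groups of cells. Circles are RNA, triangles are footprints and bars are means of 3 libraries. ABCB1 had 1 RNA count but 74 footprint counts in parental H929.

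The lines shared more calls of the same direction than independent lists would. In RNA, 1421 genes were higher in both resistant lines against 1080 for independent lists (Fisher's exact test, odds ratio 1.73, adjusted p = 2.08e-42) and 1793 lower against 1380 (1.76, 2.89e-52), while 2183 were called in opposite directions against 2460. In footprints, 199 were higher against 117 (2.14, 6.39e-16) and 260 lower against 103 (4.21, 2.73e-54), with 273 opposite against 220, so opposite calls were also more than for independent lists. In translational efficiency, 147 were higher against 45.8 (6.22, 1.79e-45) and 74 lower against 19.4 (10.5, 3.67e-31), with 31 opposite against 68.1, and DESeq2 gave 202 lower. Across genes, the fold changes of the lines had a Pearson correlation of 0.0798 in RNA, 0.0763 in footprints and 0.244 in translational efficiency (Spearman 0.109, 0.102 and 0.336). Genes are not independent replicates, in these correlations or in Fisher's test.

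Whether the change from parental to resistant cells differed between the 2 lines was tested as the difference of the changes, MM.1S minus H929. Without a further resistant derivative of either line, a response particular to a line cannot be told apart from a peculiarity of its derivative. ATF4 targets, amino acid transporters, cholesterol synthesis genes and cell cycle genes lay lower in MM.1S in RNA and in footprints. Histones lay higher in RNA and lower in footprints and in footprints per poly(A)-selected RNA. The test called 8506 of 16260 genes in RNA, 2815 of 13197 in footprints and 1178 of 8859 in translational efficiency, where DESeq2 called 1777 and a replicate block gave 679.

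In RNA, 23 of 26 ATF4 targets differed downward and 1 upward (adjusted p = 4.73e-39, and adjusted p = 0.000391 with an estimated correlation), as did 34 of 37 cell cycle genes with 2 upward (3.93e-32, and adjusted p = 1.92e-05 with an estimated correlation). Amino acid transporters differed downward for 15 of 17 (5.16e-16, and adjusted p = 0.00317 with an estimated correlation). Cholesterol synthesis genes had 20 of 25 downward and 3 upward (1.23e-10, and adjusted p = 0.00996 with an estimated correlation). Aminoacyl-tRNA synthetases had 13 of 22 downward and 4 upward (3.4e-05, and adjusted p = 0.0255 with an estimated correlation). Histones differed upward for 18 of 22 (1.05e-18, and adjusted p = 0.00336 with an estimated correlation). Upward differences of MHC class II (8 of 13, 1 downward; 0.00146), lysosome and autophagy (19 of 40, 7 downward; 0.00148) and mitochondrially encoded proteins (10 of 13; 0.0262) had adjusted p = 0.328, 0.369 and 0.643 with an estimated correlation, and the last also 0.0671 on protein-coding genes only. Adjusted over the list alone, 24 ATF4 targets were downward, 20 histones and 12 mitochondrially encoded proteins upward, and the others were the same.

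In footprints, the downward lists were cell cycle genes (28 of 37, 2 upward; adjusted p = 7.61e-31, and adjusted p = 0.000853 with an estimated correlation), histones (30 of 36; 4.98e-23, and adjusted p = 0.0142 with an estimated correlation) and ATF4 targets (17 of 25, 1 upward; 2.31e-19, and adjusted p = 0.00111 with an estimated correlation). Amino acid transporters (11 of 17; 3.24e-10, and adjusted p = 0.0115 with an estimated correlation) and cholesterol synthesis (14 of 25, 1 upward; 0.000471, and adjusted p = 0.0424 with an estimated correlation) were downward too. Aminoacyl-tRNA synthetases (12 of 22 downward; 3.11e-10), other TOP mRNAs (14 of 29 downward, 1 upward; 0.000191), ribosomal proteins (22 of 79 downward, 3 upward; 0.00668) and MHC class II (5 of 13 upward; 0.0093) had adjusted p = 0.0525, 0.157, 0.22 and 0.157 with an estimated correlation. Adjusted over the list alone, 30 cell cycle genes, 31 histones, 12 transporters, 15 cholesterol synthesis genes, 13 synthetases and 24 ribosomal proteins were downward, and 2 cholesterol synthesis genes and 2 other TOP mRNAs upward, with the others the same.

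In translational efficiency, histones, with the limit of poly(A) selection, differed downward for 17 of 17 (adjusted p = 3.42e-101, and adjusted p = 3.56e-09 with an estimated correlation) and BCL2 family genes upward for 3 of 9 (0.00448, and adjusted p = 0.041 with an estimated correlation). Other TOP mRNAs (12 of 29 downward; 5.64e-07), ribosomal proteins (16 of 78 downward, 2 upward; 0.000158), synthetases (6 of 22 downward; 0.00102) and cell cycle genes (12 of 35 downward, 2 upward; 0.0139) had adjusted p = 0.0954, 0.751, 0.111 and 0.0954 with an estimated correlation. Mitochondrially encoded proteins (5 of 13 downward, 1 upward; 0.0275) and ribosome biogenesis factors (8 of 50 downward, 1 upward; 0.0435) had adjusted p = 0.583 and 0.338 with an estimated correlation, and the latter 0.0635 on protein-coding genes only. Adjusted over the list alone, 16 other TOP mRNAs, 22 ribosomal proteins, 12 synthetases, 14 cell cycle genes, 6 mitochondrially encoded proteins and 10 biogenesis factors were downward, 4 cell cycle genes and 2 biogenesis factors upward, and the others the same.

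Of the genes named in advance, differences did not pass in RNA for MTOR at 0.27 ± 0.13 (adjusted p = 0.0934), MYC at -0.04 ± 0.12 (0.817) and RPS6 at -0.02 ± 0.15 (0.97). MTOR passed without replicate 2 of resistant MM.1S or replicate 1 of parental H929 (0.0485 and 0.0267). In footprints MTOR at 0.13 ± 0.20 (0.686), RPL3 at -0.32 ± 0.30 (0.505), MYC at -0.01 ± 0.20 (0.998), IRF4 at -0.30 ± 0.18 (0.264), DEPTOR at -0.25 ± 0.21 (0.438) and RPS6 at -0.74 ± 0.29 (0.0815) did not pass. RPS6 passed with DESeq2 (0.0481), on protein-coding genes only (0.0444) and without replicate 1 of resistant H929 (0.0272). In translational efficiency MTOR at -0.17 ± 0.25 (0.69), RPL3 at -0.72 ± 0.34 (0.165), MYC at -0.01 ± 0.23 (0.986), MCL1 at 0.00 ± 0.25 (0.995), IRF4 at 0.15 ± 0.20 (0.662), EIF4EBP1 at -0.50 ± 0.43 (0.476), RPS6 at -0.77 ± 0.34 (0.132), DDIT4 at -0.45 ± 0.47 (0.562) and DEPTOR at 0.44 ± 0.23 (0.206) did not pass. RPL3 passed without replicate 3 of the parental MM.1S footprints (0.00793) and RPS6 without replicate 1 of the resistant H929 footprints (0.0417). ABCB1 was not tested in translational efficiency between lines.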

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

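The tests of differences between lines per gene were planned, while the list tests of those differences and all tests of explanations were chosen after results were seen. Each value here was singled out because the change with resistance differed between MM.1S and H929 in a test of the difference itself, given as MM.1S minus H929 on the log2 scale. That test called 8506 genes in RNA, 2815 in footprints and 1178 in translational efficiency.

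List medians differed in RNA by -0.50 for aminoacyl-tRNA synthetases, -2.17 for ATF4 targets, -1.05 for cholesterol synthesis, -1.68 for cell cycle genes, -1.56 for amino acid transporters and 3.71 for histones. In footprints they differed by -1.82 for ATF4 targets, -0.82 for cholesterol synthesis, -2.07 for cell cycle genes, -1.54 for histones and -1.71 for amino acid transporters. In translational efficiency they differed by 0.74 for the BCL2 family and -5.14 for histones, whose ratio is to polyadenylated RNA only.

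The largest single differences in RNA were RIMBP2 at 12.43, PXDN at 10.96, TRPM2 at 9.82 and AJAP1 at 9.13 upward, and PTPRC at -14.65, ABCB1 at -11.80, IFTAP at -9.98 and LINC01234 at -8.36 downward. Fitted sizes of genes near 0 counts in a group, such as RIMBP2, PTPRC and ABCB1, depend on the prior count. Among genes named in advance, DDIT4 differed by -3.73, TXNIP by 3.26, EIF4EBP1 by -1.74, DEPTOR by -0.73, MCL1 by 0.67, IRF4 by -0.49, RPL3 by 0.36 and ATF4 by -0.26. RPL3 lost its call without replicate 2 of parental MM.1S (adjusted p = 0.0573) or replicates 1 and 2 of parental H929 (0.0786 and 0.0554). ATF4 lost it in 9 of 12 cases of leaving out 1 library (0.0513 to 0.0951), all but replicate 1 of parental MM.1S and replicates 1 and 2 of parental H929.

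In footprints the largest differences were RAMACL at 8.73, ADGRE1 at 8.04, CDC42P6 at 7.73 and COL13A1 at 6.04, and RPL7P9 at -12.93, TUBBP2 at -12.77, TLR7 at -10.72 and RNU4ATAC10P at -10.66. CDC42P6, RPL7P9, TUBBP2 and RNU4ATAC10P are pseudogenes whose reads can come from their parent genes, so these are uncertain. RAMACL was at 2.10 without replicate 2 of parental H929 (adjusted p = 1) and lost its call in 8 other cases (0.0516 to 0.0659), all but replicate 3 of parental MM.1S and replicates 1 and 3 of parental H929. COL13A1 was at 3.24 without replicate 2 of resistant MM.1S (adjusted p = 1) and lost its call in 8 other cases (0.0515 to 0.0711), all but replicates 1 and 3 of resistant MM.1S and replicate 2 of resistant H929. RPL7P9 lost its call in 9 cases (0.0534 to 0.0783), all but replicate 3 of resistant MM.1S, replicate 2 of parental MM.1S and replicate 2 of resistant H929. ADGRE1 was at 6.46 without replicate 1 of parental H929 (0.16), and TLR7 at -5.75 without replicate 3 of resistant H929 (adjusted p = 1). ABCB1 differed by -3.95, with a call lost without replicates 2 or 3 of parental MM.1S (0.063 and 0.118). DDIT4 differed by -4.10, TXNIP by 2.75, EIF4EBP1 by -2.19, ATF4 by -0.95 and MCL1 by 0.71. MCL1 lost its call without replicate 2 of resistant or parental MM.1S (0.0552 and 0.0595) or any replicate of parental H929 (0.056, 0.0511 and 0.0561).

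In translational efficiency the largest differences were GFOD1 at 7.39, IFTAP at 4.92, LAPTM4B at 4.20 and BMPR1A at 4.12, and NAMPTP1 at -9.54, H2AC8 at -7.24, H2BC21 at -6.99 and RPS10-NUDT3 at -6.84. NAMPTP1 is a pseudogene, H2AC8 and H2BC21 have near-identical copies and RPS10-NUDT3 overlaps other genes, so their values are uncertain. IFTAP was at -0.10 without replicate 1 of the resistant MM.1S footprints (adjusted p = 1) and lost its call without replicates 1 or 3 of the resistant MM.1S RNA (0.0516 and 0.0546). LAPTM4B was at 2.57 without replicate 2 of the resistant MM.1S footprints (0.282) and lost its call without replicate 3 of the resistant MM.1S RNA (0.0523). RPS10-NUDT3 lost its call without replicates 1 or 3 of the resistant H929 footprints (0.0814 and 0.0729). ATF4 differed by -0.72 and TXNIP by -0.55. Over the 24 libraries left out in turn, ATF4 lost its call for replicates 1 and 2 of the resistant MM.1S footprints, replicate 1 of the parental and of the resistant H929 footprints, replicate 3 of the resistant MM.1S RNA, replicate 2 of the parental H929 RNA and replicates 1 and 2 of the resistant H929 RNA (0.051 to 0.0678). TXNIP lost it for replicate 2 of the resistant and replicate 1 of the parental MM.1S footprints, replicates 1 and 3 of the parental H929 footprints, replicates 1 and 2 of the parental and 2 and 3 of the resistant MM.1S RNA, and replicate 2 of the parental and 2 and 3 of the resistant H929 RNA (0.0522 to 0.068).

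The gain of footprints per RNA on ribosomal protein mRNAs, a list call that held with an estimated correlation in H929 (adjusted p = 0.00286) but not in MM.1S (0.196), was weighed first. Summed with pseudogenes the change was 1.33 ± 0.15 in MM.1S and 1.5 ± 0.16 in H929, against 1.32 ± 0.15 and 1.47 ± 0.16 without them, which argues against reads shared with pseudogenes as the cause. A higher ratio of footprints to RNA on TOP mRNAs as a class may account for it in H929, where other TOP mRNAs had an adjusted p = 0.00286 with an estimated correlation, and stays open in MM.1S (0.595). Less RNA was part of this ratio. Medians of other TOP mRNAs were -0.49 in RNA and 0.50 in footprints in H929. In MM.1S they were -0.45 and -0.09, and 5 of 29 rose and 7 fell in footprints, so these did not rise there as a set. Coding length was not tested.

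ABCB1 footprints in parental H929, 4.62% of those in the resistant line with 1 RNA count, were weighed next. RNA was near 0 in 1 state of a line for 7 other genes: RIMBP2, MMP9, CD33, SLC6A15, ESRP1, INHBE and PTPRC. They had at most 9 RNA counts there, and at least 5 CPM and 100 footprints in the other state, limits set after an exploratory look. Their median share was 3.15% (1.18% to 7.77%), as footprints carried over between libraries of a line could give. Only PTPRC, at 7.77%, came from H929 and the others from MM.1S, so for H929 this rests on 1 gene. The shares are of pooled counts not scaled to depth, which differed between groups. Scaled, ABCB1 had a ratio of 15.4 between resistant and parental footprints. Among 47 genes near 0 in 1 line and at least 20 CPM in the other, the median was 0.307% and the highest 4.53%, close to the share of ABCB1. The median was lower than within a line, but this does not settle whether carry-over was even among all footprint libraries. These genes had a higher CPM limit and pooled more libraries, and the bound was replaced after a first one had left the question open. The 12 tested genes within 1 Mb of ABCB1 had a median RNA change of 0.00 (-1.21 to 1.83), 3 higher and 2 lower, so they did not rise as a set. The bound for a gain of the whole region as the full cause was a change of neighbours comparable to that of ABCB1. A gain could hardly reach it, so this test decides little, and a gain as part of the cause stays open. A change confined to ABCB1 with resistance stays open, and was not tested.

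Histone RNA in resistant MM.1S, higher without more footprints, was weighed last. A set of 12 small structural RNAs without poly(A) tails had a median change of -0.32 (-2.69 to 2.13) against a histone lower quartile of 2.77. This argues against a rise of tail-less RNA of all kinds in these libraries as the full cause. The set holds no mRNA, so it cannot tell whether more tail-less histone mRNA entered the libraries. Small structural RNAs took somewhat more of the counts in the resistant libraries (1.49% to 1.67%) than in the parental (1.08% to 1.33%). Summed RNA of the listed histone genes changed by 4.10 ± 0.10, which argues against counts moved among these genes, while their summed footprints changed by -0.61 ± 0.09. Histone genes outside the list were not in the sum. In H929 summed RNA changed by -0.32 ± 0.09 and footprints by 0.88 ± 0.03. Summed histone RNA was at 749 ± 80.2 CPM in parental and 597 ± 17.6 CPM in resistant H929 (SD, n = 3). Both were above resistant MM.1S (342 ± 11.8 CPM), and parental MM.1S was the lowest group (20.1 ± 2.37 CPM). The difference in polyadenylated histone RNA between parental and resistant MM.1S may be biological, a hypothesis found and tested on the same data.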

How the results depend on the processing

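Fits on protein-coding genes, list tests without replicate 2 of the resistant H929 footprints, list tests on differences between lines and all tests of other splits were chosen after the data were seen. Of 4934 values of named genes under an alternative, 4747 had the same direction and side of the threshold, 115 lost and 11 gained a call and 61 changed sign. Of 462 list values, 403 were the same and 59 lost their call, 50 of them with an estimated correlation, and none changed sign. Of 152 counts of calls, 138 stayed within 1.5 times. No scaling moved the median of all genes by over 0.1. Each scaling centres most genes near 0, so this could not show a change shared by all genes. In simulated footprints with 200 changed genes, 2-fold changes were recovered for 11.9% of changed genes in MM.1S and 7.94% in H929. These simulations gave 45 and 41 calls against 5094 and 1139 real ones, which makes their adjusted threshold stricter. The shares therefore need not hold for the real footprints, where changes of that size may still be missed.

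Leaving out 1 library gave 9311 to 9671 calls for RNA in MM.1S and 6976 to 7881 in H929, 4130 to 4970 for footprints in MM.1S and 2658 to 4228 for translational efficiency in MM.1S. H929 footprints (1139) had 621 to 1231, with 660, 637 and 621 without parental replicates 1, 2 and 3 and 742 and 668 without resistant replicates 1 and 3. H929 translational efficiency (402) had 230 to 850, with 850 without resistant footprint replicate 2 and 230 and 259 without resistant RNA replicates 1 and 2. Differences between lines had 7938 to 8504 in RNA, 2165 to 2935 in footprints and 883 to 1539 in translational efficiency. DESeq2 called 762 (59.7% higher, against 71.9%) in H929 translational efficiency, 1777 in its difference between lines (1178) and 202 shared lower genes (74). Of 76 list calls within lines, 39 held with an estimated correlation. The cause was not tested.

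Same-numbered libraries did not deviate together: in 1 of 12 pairs of groups every pair correlated above 0.1, so the numbers were not taken to pair the libraries. A replicate block gave 648 calls in H929 footprints, 240 in H929 translational efficiency and 679 in the difference of translational efficiency, with no other count moved by over 1.5 times. It reversed ABCB1 in MM.1S footprints (0.14) and ended 9 calls of named genes: MCL1 (adjusted p = 0.121) and ATF4 (0.0768) in H929 footprints, MRPL37 (0.0839) in H929 translational efficiency, and, in differences between lines, ATF4 in RNA (0.0803), RPL7P9 (0.0589) and MCL1 (0.0663) in footprints and RPS10-NUDT3 (0.105), TXNIP (0.114) and ATF4 (0.0813) in translational efficiency. It also ended 3 list calls: plasma cell identity in MM.1S RNA (0.105), erythroid and megakaryocyte markers in H929 RNA (0.12) and ribosome biogenesis factors in the difference of translational efficiency (0.0567).

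Other settings ended these calls. No filter ended ANXA1 in H929 footprints (0.105), MTOR in MM.1S (0.0582) and MRPL37 in H929 translational efficiency (0.0835), and the differences of RPL7P9 in footprints (0.0624) and of TXNIP (0.116) and ATF4 (0.0845) in translational efficiency. Fits with other samples ended ANXA1 in H929 footprints (0.0953) and MIGA1 (0.208) and MRPL37 (0.0776) in H929 translational efficiency. Other size factors ended MCL1 in H929 footprints (0.0522). Fits on protein-coding genes ended the difference of TXNIP in translational efficiency (0.0566), ATF4 targets and cholesterol synthesis in H929 footprints (0.051 each), and the differences of mitochondrially encoded proteins in RNA (0.0671) and ribosome biogenesis factors in translational efficiency (0.0635).

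Apart from IFTAP, named genes that changed sign had values near 0 and were not past the threshold; the cause was not tested. In MM.1S footprints, leaving out 1 library gave -0.62 to 0.54 for ABCB1 (-0.02), -0.14 to 0.06 for MYC (-0.04) and -0.38 to 0.06 for RPL3 (-0.15), and no filter gave 0.07 for ABCB1 and 0.05 for MYC. In H929 footprints MTOR (0.09) had -0.01 to 0.18 and MYC (-0.03) -0.08 to 0.06. In MM.1S translational efficiency MCL1 (-0.04) had -0.15 to 0.15 and 0.01 with no filter, IRF4 (0.05) -0.04 to 0.16 and DDIT4 (0.09) -0.43 to 0.49, and in H929 MCL1 (-0.03) had -0.12 to 0.04. In differences between lines, MYC (-0.04) had -0.13 to 0.04 and RPS6 (-0.02) -0.19 to 0.02 in RNA. MYC (-0.01) had -0.12 to 0.09 in footprints and 0.08 with no filter. In translational efficiency MYC (-0.01) had -0.12 to 0.08, 0.05 with no filter and 0.06 on protein-coding genes, MCL1 (0.00) had -0.12 to 0.20 and IFTAP (4.92) -0.10 to 5.53, with -0.10 without replicate 1 of the resistant MM.1S footprints.

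Other splits of the same libraries were counted. In RNA and footprints within a line, 1 of 10 splits, the real one, gave as many calls, which is too few splits for a share under 0.05. The real counts and highest others were 9936 and 0 (RNA, MM.1S), 8063 and 0 (RNA, H929), 5094 and 0 (footprints, MM.1S) and 1139 and 1 (footprints, H929). Of 100 splits drawn, 2 gave as many calls for MM.1S translational efficiency (3558, highest other 6980), 4 for H929 (402, 4381), 2 for the difference in RNA (8506, 9533), 2 for that in footprints (2815, 3776) and 4 for that in translational efficiency (1178, 3970). These shares are under 0.05, but the splits regroup the libraries of each line and assay, so they test only whether no line and assay changed with state. They cannot tell whether the difference of changes behind each of the 5 counts arose by chance. Chance differences between cultures are not covered if libraries of a group came from 1 culture, which the labels do not settle. Each other split as large kept the libraries of at least 1 line and assay in their real groups, with the groups of another turned round or mixed, and so carried a real change into the difference. Splits that kept none gave at most 2 calls. The splits do not show whether a call in translational efficiency comes from RNA or from footprints.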

Other observations

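Of the fixed marker lists of other cell types, the erythroid and megakaryocyte list passed in H929 RNA (camera adjusted p = 0.000639, but 0.12 with a replicate block) and not in MM.1S (0.0687), with no difference between lines past the threshold (0.75). The other 4 lists and MHC class I presentation did not pass in RNA of either line. In MM.1S and H929, B cell markers had 5 and 2 of 10 members higher and 3 and 2 lower (camera adjusted p = 0.254 and 0.681). T and NK cell markers had 0 and 2 of 4 higher and 1 lower in each (0.616 and 0.136), myeloid markers 1 and 2 of 7 higher and 3 lower in each (0.502 and 0.768), and stromal markers 1 of 6 higher in each and 3 and 2 lower (0.32 and 0.682). MHC class I presentation had 8 and 5 of 15 higher and 2 and 5 lower (0.0744 and 0.549). Principal components 1, 2 and 3 held 77.5%, 11.6% and 5.65% of the variance of RNA libraries.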
